A study of Drosophila melanogaster with 46 samples.

How the data were processed

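The series measured chromatin accessibility by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in imaginal discs of Drosophila melanogaster larvae. It has 46 samples. The 31 libraries analysed here came from eye-antennal discs of inbred lines of the Drosophila Genetic Reference Panel (DGRP), a collection of strains derived from a wild population. The other 15 samples (reporter insertions, sorted Optix-GFP cells and Grainyhead ChIPmentation) are not analysed here.

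The deposited values are raw counts of reads per region over 1 merged set of 30774 regions, with 1 column per library. The submitters' processing notes name Bowtie2, MACS2, featureCounts and DESeq2 and the genome build dm3, with no versions. The treatment of duplicate reads, of reads with several matches and of the offset of the transposase cut is not given in the sources used here, and each of these can move counts in repeated sequence or at region edges. All coordinates are those of the deposited regions on dm3. No genome or annotation of that build was used here and the gene table at hand belongs to another assembly, so regions are named by position, with no gene, exon or intron. For the same reason the planned comparison of regions with and without a Grainyhead motif and the planned gene list tests were not run.

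Samples were grouped by the line named in their titles. Of 23 lines, 8 have 2 libraries and 15 have 1. Some titles carry the suffix IR, whose meaning the labels do not give. It is used only as a label of a library. It occurs on 15 libraries and is missing from 16, and each line with 2 libraries has 1 of each kind. Replicate 1 is the library without the suffix in these 8 lines. The shared line name pairs the 2 libraries. The labels do not say whether the 2 came from separate dissections, so p-values measure the spread between these libraries, which may be technical. The counts of the 2 libraries of a line differed by far more than sampling noise, with a chi-square per degree of freedom from 8.52 to 29.4 over the 8 lines, and they were kept as separate libraries.

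Library totals ranged from 1110755 to 12758783 counts with a median of 6283136. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only.

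Counts were analysed with edgeR 4.0.16 in R 4.3.3. Regions were kept where the CPM (counts scaled to the library total) reached the value of 10 counts at the median library size in at least 2 libraries. TMM normalization and robust quasi-likelihood F-tests were used with Benjamini-Hochberg adjustment, at a threshold of 0.05. For differences between lines, all line coefficients were tested together in the 31 libraries with a term for the suffix, which leaves 7 residual degrees of freedom, all from the 8 lines with 2 libraries. For the suffix, the 16 libraries of those 8 lines were fitted with the line as a block, which also leaves 7. Each line was also set against the mean of the other 22 in the first model. A line with 1 library borrows the spread of the lines with 2. Log2 CPM values carry a prior count of 2.

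Repeatability was the correlation between the 2 libraries of a line of their deviations from the mean of their suffix group, over regions above the median level, set against the 56 cross-line pairs by an exact one-sided permutation test over all 40320 pairings. Shares by chromosome arm were compared with Fisher's exact test. The ratio of the mean count per region on X to that on arms 2L, 2R, 3L and 3R was computed per library. Correlations of line means were taken by distance over the called regions and over 4000 tested regions drawn at random. Regions and pairs of regions are not independent replicates.

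Regions named in the text were chosen by a rule. Among regions called between lines it took the 10 with the smallest p, the 10 with the largest SD of line means among those above the median level, and up to 6 in each direction in which 1 line lay at least 4-fold away from every library of all other lines. For the suffix it took the 5 with the smallest p in each direction. The tests, this rule and the alternatives were fixed before the data were examined. Alternatives that use principal components of the libraries (log2 CPM, regions above the median level) or a loess fit on mean abundance were chosen after seeing the data. DESeq2 1.42.0 and limma 3.58.1 served as other tests.

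The tests were tried on simulated counts with 50 regions changed at each of 4 fold sizes. The changed regions were drawn only from those at or above a minimum mean count, and all regions had the same dispersion. The rates below therefore do not give the power over all regions of the real data. In the simulated line comparison, each change was given to many lines drawn at random, so recovery of a change in a single line was not tried. Over 30774 regions, 92% of 2-fold and 100% of 4-fold changes were recovered, with 8 false among 204 calls. With a component across libraries of the kind seen in the data added and left out of the model, 0% of 2-fold, 40% of 4-fold, 78% of 8-fold and 86% of 16-fold changes were recovered over 30771 regions, with 0 false among 102 calls. With the component in the model, 92% of 2-fold and 100% of 4-fold changes were recovered over 30772 regions, with 12 false among 208 calls. The component added was the first principal component alone, which favours the model that includes it. In the simulated suffix comparison with the component left out of the model, 48% of 2-fold and 78% of 4-fold changes were recovered over 30757 regions. With the component in the model the values were 76% and 100% over 30761 regions, with 14 false among 202 calls.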

Results

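Accessible chromatin was profiled by ATAC-seq in eye-antennal discs, the larval tissue that forms the eye and antenna, of wandering larvae from 23 DGRP lines. The series set out to find loci at which DNA differences between strains go with differences in accessibility. The 31 libraries comprised 2 libraries for each of 8 lines and 1 for each of 15 lines. Counts were given for 30774 regions on dm3, with 5983 on 2L, 5570 on 2R, 6374 on 3L, 7165 on 3R, 247 on chromosome 4 and 5435 on X. Regions were 201 to 3395 bp long with a median of 456 bp. The shallowest library was replicate 1 of line DGRP_25208 with 1110755 counts and the deepest was that of line DGRP_28206 with 12758783.

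The question of the first comparison was which regions differ in accessibility between lines. Some of the regions that differed had line means in separate low and high ranges. The region on 3L from 15290369 to 15291043 had line means between -0.15 and 3.01 log2 CPM in 10 lines and between 5.74 and 7.88 in the other 13, against a within-line SD of 0.57 (edgeR adjusted p = 0.0093). The 2 libraries of a line differed there by up to 2.27 log2 units, in DGRP_28265. The within-line SD was 1.52 with the first principal component of the libraries removed, a step chosen after seeing the data. That removal had no term for the line, so differences between lines can enter it and raise this SD. With the line and that component in 1 model, also chosen after seeing the data, the edgeR adjusted p was 3.4e-08. The region on 2R from 10761171 to 10761797 was lowest in lines DGRP_25194 and DGRP_28123, at -0.55 and 0.17 log2 CPM, and lay between 5.09 and 6.36 in the other 21 lines (within-line SD 0.31, edgeR adjusted p = 0.0156). These low values rest on 3 reads in DGRP_25194 and on 3 and 6 in the libraries of DGRP_28123. The DNA sequence of the lines was not examined here, so low counts do not by themselves show closed chromatin. On 2L from 5805093 to 5805826, the 5 lines DGRP_29651, DGRP_28153, DGRP_25174, DGRP_28265 and DGRP_28123 lay between 1.93 and 3.16 log2 CPM and the other 18 between 5.64 and 6.55 (within-line SD 0.40, edgeR adjusted p = 0.0259).

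**Figure D1:**
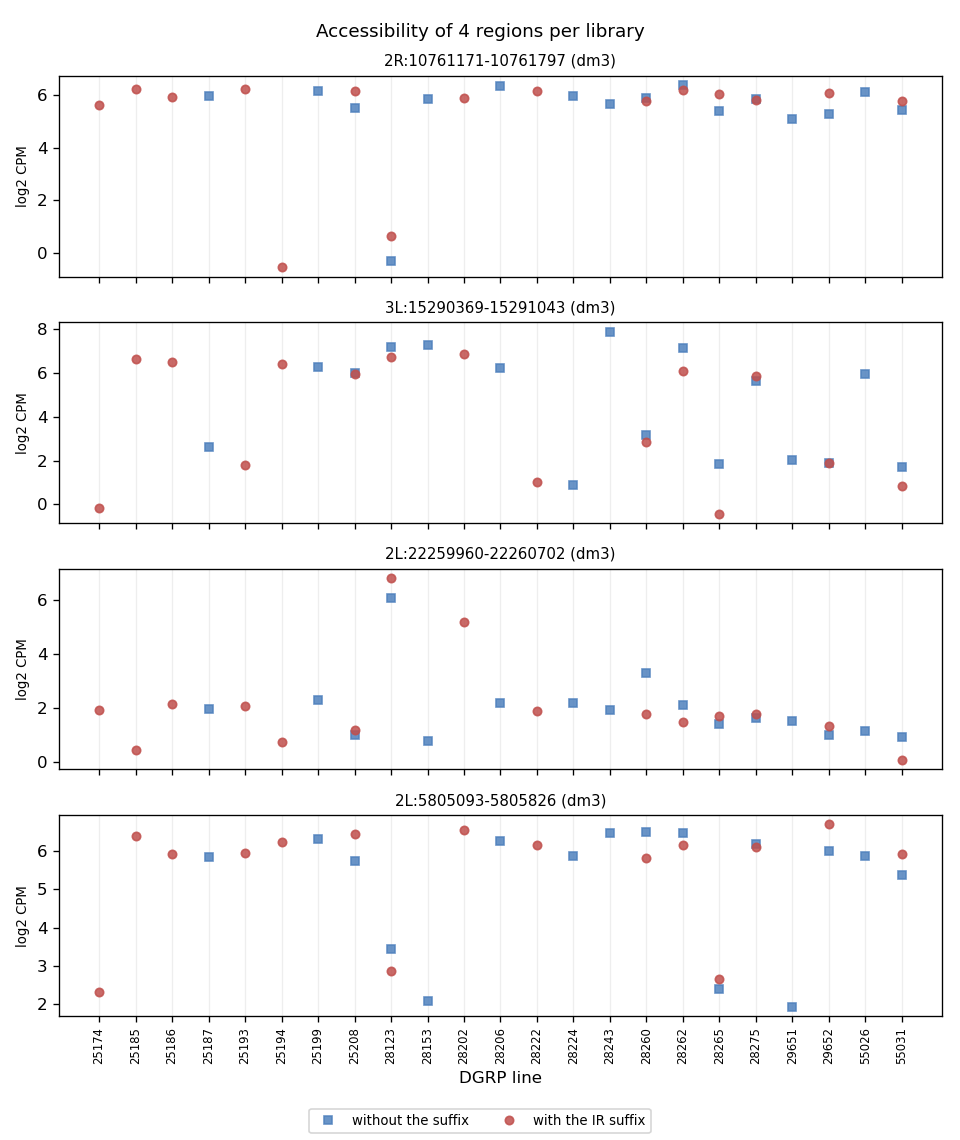
Log2 CPM of 4 regions (y axes) in each of the 31 libraries by DGRP line (x axis), with 1 point per library, squares for libraries without the IR suffix and circles for those with it. Lines separate by up to 8.04 log2 units on 3L from 15290369 to 15291043, lines DGRP_25194 and DGRP_28123 stand apart on 2R from 10761171 to 10761797, and lines DGRP_28202 and DGRP_28123 on 2L from 22259960 to 22260702.

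A few regions had high counts mainly in 1 line. Line DGRP_25194, which has a single library, reached 6.40 log2 CPM on 3L from 23829682 to 23831039, where the other 22 lines lay between 0.37 and 3.99, and 6.13 on X from 19336717 to 19337996, where they lay between 0.04 and 3.84 (edgeR adjusted p = 0.0153 for both). The line means of these 2 regions correlated with r = 0.958, and whether the regions share reads was not tested. Line DGRP_28123, with 2 libraries, had a mean of 6.21 on 3L from 14069627 to 14070290 against 2.82 to 3.98 in the other lines (edgeR adjusted p = 0.0259). On 2L from 22259960 to 22260702, lines DGRP_28202 and DGRP_28123 lay between 5.19 and 6.46 and the other 21 between 0.46 and 2.54 (edgeR adjusted p = 0.0153). Each of these p comes from the joint test of all lines and does not set the named lines against the rest. No region met the rule for a region low in 1 line alone.

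The other named regions separated lines less sharply. On 2L from 20106601 to 20107049, 8 lines lay at or below 3.60 log2 CPM and 15 at or above 4.81. On 2L from 20114919 to 20115452, 6 lines lay at or above 5.31 and 17 at or below 3.19. On 3L from 23032175 to 23032823, lines DGRP_25199, DGRP_28260, DGRP_25185, DGRP_25174 and DGRP_25194 lay at or above 4.47 and the rest at or below 2.83. On 3L from 12917437 to 12917843, lines DGRP_28123, DGRP_28224 and DGRP_25208 lay at or below 0.30 and the rest at or above 1.36. Line DGRP_25193 was highest at 8.63 on 2L from 22675596 to 22676596, where line means began at 3.86. Line DGRP_28222 was highest in 3 regions, at 6.47 on 3L from 22093911 to 22094492, 6.78 on 2R from 14464341 to 14465069 and 7.04 on X from 323469 to 324312. Line DGRP_25185 was lowest at 2.90 on 3R from 20280803 to 20282349, and line DGRP_28260 at 2.18 on 2L from 21656141 to 21657018. Each passed the same edgeR test.

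In all, 29 of 30773 tested regions passed, and 2363 had an unadjusted p under 0.05. This count changed with the model. It was 0 with the X to autosome ratio as a covariate, between 0 and 41 when single libraries of the 8 replicated lines were left out, 1697 with DESeq2, and 3207 with the first principal component of the libraries as a covariate, a setting chosen after seeing the data. It was 0 or 1 without either library of DGRP_25208, DGRP_28275 or DGRP_29652 or without replicate 2 of DGRP_28123 or DGRP_55031. The 29 regions were among the 3207.

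The libraries differed widely along that first component, which held 40.0% of the variance. Scores ran from -69.7 to 37.8. From the lowest to the highest score, the fitted level fell at least 4-fold in 3807 regions and rose as much in 1. The 1 that rose, on 3L from 15290369 to 15291043, followed the score only weakly (r = 0.318). The fitted level fell at least 2-fold in 6752 regions and rose as much in 1269, and the median change was 0.25 on the log2 scale. The level on 2L from 17560215 to 17560935, the steepest of these, fell by 6.11 on the log2 scale (r = -0.973). The 2 libraries of a line had scores on opposite sides of 0 in 5 of 8 lines and on the same side in DGRP_28123 (32.2 and 14.3), DGRP_28262 (30.1 and 22.0) and DGRP_28275 (-28.7 and -36.5). Replicate 1 of line DGRP_25208 scored -53.4 and replicate 2 scored 37.8, while line DGRP_28260 went the other way, from 31.4 to -36.8.

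**Figure D2:**
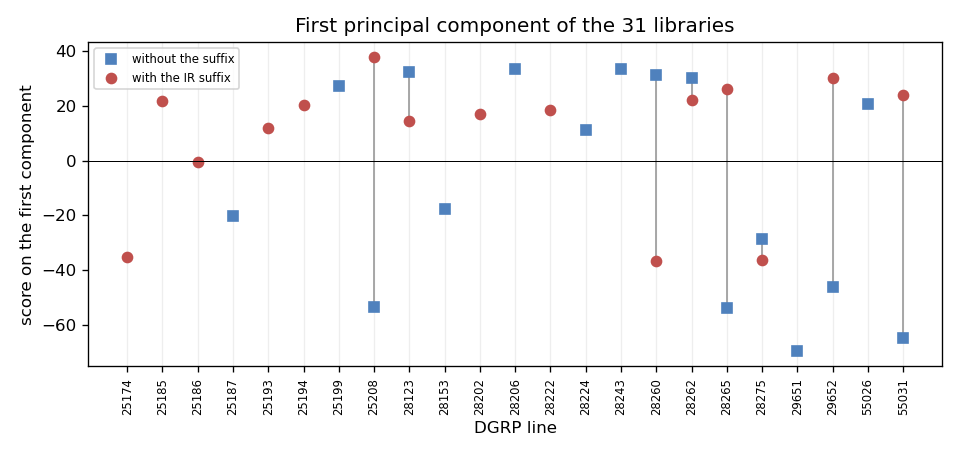
Score on the first principal component (y axis) of each of the 31 libraries by DGRP line (x axis), with 1 point per library and a grey line joining the 2 libraries of a line. Scores run from -69.7 to 37.8, and the 2 libraries of lines DGRP_25208, DGRP_28260, DGRP_28265, DGRP_29652 and DGRP_55031 lie on opposite sides of 0.

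The next comparison set each line against the mean of the other 22. Among lines with 2 libraries, line DGRP_28262 had 166 regions past the threshold (159 higher), line DGRP_28123 had 161 (114 higher) and line DGRP_29652 had 95 (64 higher; edgeR adjusted p under 0.05). The single library of DGRP_25185 had 279, of which 262 were higher. For a line with 1 library the fit assumes the spread of the replicated lines, and the count does not separate the line from that library. The median over lines was 15 and line DGRP_28206 had 0, with 1399 regions at an unadjusted p under 0.05. The sum over lines was 983. It was 8039 with the first component as a covariate, with 1476 for the library of DGRP_25185.

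Whether a line's profile recurs in its second library was tested over 8 lines. The mean correlation between the 2 libraries of a line was 0.066 against -0.021 for libraries of unlike lines (exact one-sided permutation p = 0.322). The values ranged from -0.41 in line DGRP_28260 to 0.55 in line DGRP_28275. Without line DGRP_28260 the excess over unlike lines was 0.216 (exact permutation p = 0.0024). That line had the lowest value, so leaving it out raises the mean in any case. Without any other single line the excess was 0.0173 to 0.111 (exact permutation p from 0.267 to 0.554). With the first component removed, a step chosen after seeing the data, the mean was 0.359 against -0.049 (exact permutation p = 2.48e-05, the smallest that 40320 pairings can give). The correlation rose in 5 lines and was lower than before in DGRP_28123 (0.211 to 0.175), DGRP_28262 (0.431 to 0.312) and DGRP_28275 (0.549 to 0.330). In DGRP_28123 it lay below its highest value with an unlike line, 0.224.

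**Figure D3:**
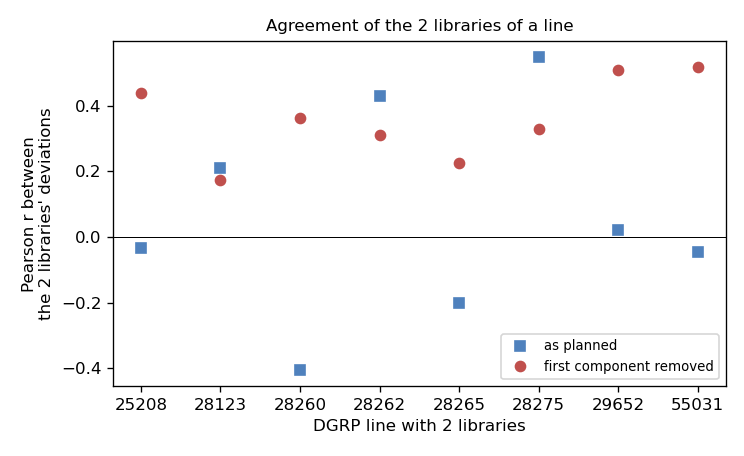
Pearson r between the 2 libraries of a line (y axis) for the 8 lines with 2 libraries (x axis), each library taken as deviations from the mean of its suffix group, as planned (squares) and with the first component removed (circles). Values as planned run from -0.41 to 0.55, and with the component removed from 0.175 to 0.518.

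The libraries with and without the IR suffix were compared within the 8 lines that have both. All 9 regions that passed were higher with the suffix, each in 8 of 8 lines. The strongest lay on 3L from 19630225 to 19630593, with a log2 fold change of 1.81 (SE of the paired difference 0.128, edgeR adjusted p = 0.00176). A second called region lay beside it, on 3L from 19629692 to 19629988, with a log2 fold change of 1.56 (SE 0.218). It was not among the regions the rule takes and was named after its values were seen. The others that the rule takes were on 3R from 14751761 to 14752075 (log2 fold change 1.60, SE 0.113, edgeR adjusted p = 0.0286), on chromosome 4 from 930571 to 931431 (1.18, SE 0.118, edgeR adjusted p = 0.0286), on 2R from 14058639 to 14059257 (1.23, SE 0.142, edgeR adjusted p = 0.0324) and on 2L from 12718625 to 12719536 (1.05, SE 0.083, edgeR adjusted p = 0.0363). Of 30710 regions tested, 5229 had an unadjusted p under 0.05. Leaving out single libraries gave a count of 3 for either library of DGRP_28260 and 1 for each of the other 14. With the line as a block, a left-out library takes its whole line out of the comparison. The 2 libraries of a line are thus not separate checks. Without the line as a block in the same 16 libraries the count was 142. With the X to autosome ratio as a covariate 1 region passed, and with DESeq2 1114 did (816 higher, 298 lower). When the first component was a covariate, a setting chosen after seeing the data, 488 regions were higher and 747 lower, and the 9 were among them.

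The share of line-differing regions did not differ detectably between arms. It was highest among the large arms on 3L, at 9 of 6374 regions or 0.141% (exact 95% interval 0.0646% to 0.268%), and lowest on 3R, at 3 of 7165 or 0.0419% (0.00864% to 0.122%). The smallest adjusted p by Fisher's exact test was 0.371. In the fit with the first component the share was 11.9% on 2L (adjusted p = 0.000149), 11.7% on X (adjusted p = 0.00227) and 8.39% on 3R (adjusted p = 3.17e-10), each against the other arms. Fisher's test takes regions as independent, but called regions of this fit up to 1000 bp apart had a mean correlation of 0.751. These p-values can therefore be too small. The X to autosome ratio was not a term in that fit.

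The ratio of X to autosomal counts per region had a median of 0.955 and ran from 0.708 in replicate 1 of line DGRP_28262 to 1.08 in replicate 1 of line DGRP_29652, with an SD of 0.106 over the 31 libraries. The 2 libraries of a line differed by 0.158 on average and by up to 0.253 in line DGRP_28265. The ratio was lower with the suffix in 5 of 8 lines.

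Line means of neighbouring regions varied together. Over 4000 of the tested regions, pairs up to 1000 bp apart had a mean correlation of 0.444 over the 23 lines, pairs 5000 to 10000 bp apart 0.178, and pairs on different arms -0.0010. These line means keep the first component and the suffix, and 15 of the 23 lines have 1 library. The values therefore do not tell differences between lines from differences between libraries. The 29 called regions held only 1 pair within 10000 bp, on 2L at 20106601 and 20114919, whose line means ran against each other (r = -0.87, rho = -0.55, adjusted permutation p = 0.000272 for r and 0.16 for rho over 136 pairs of named regions, and r = -0.84 without the 2 lines farthest from the median). Lines fall into separate clusters in each of these 2 regions, so these values describe the pair only. Among regions called with the first component as a covariate, the mean was 0.751 up to 1000 bp and 0.020 between arms. Line means of that set were taken after the first component and the suffix were removed. It thus differs from the 4000 regions in both selection and measure, and the 2 sets are not directly comparable.

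**Figure D4:**
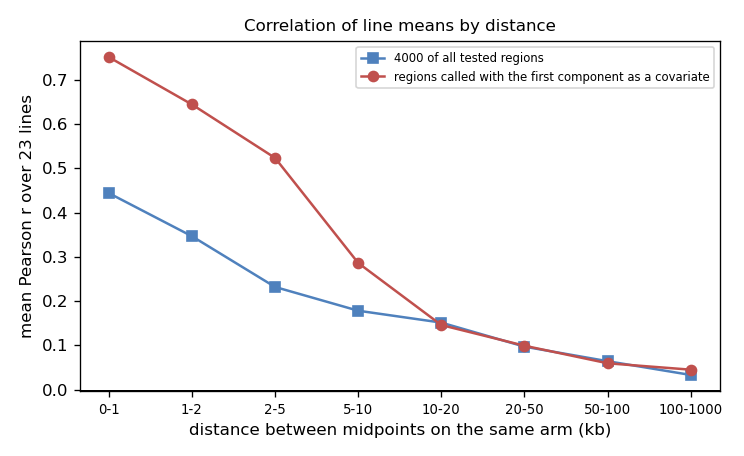
Mean Pearson r of line means over 23 lines (y axis) by distance between region midpoints on the same arm in kb (x axis), for 4000 of all tested regions (squares) and for the regions called with the first component as a covariate (circles). The mean falls from 0.444 to 0.033 in the first set and from 0.751 to 0.045 in the second. Line means of the second set only were taken after the first component and the suffix were removed.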

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

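The tests of the first component against abundance, line and suffix below were chosen only after the result was seen.

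In 24 sets of 8 values, 2 stood apart from the others, where chance sets apart about 1 in 20. Among the 8 libraries with the suffix, replicate 2 of line DGRP_29652 had 11840103 counts against 6283136 in the next and a median of 4758491. In the same 8 libraries, the X to autosome ratio of replicate 2 of line DGRP_25208 was 1.01, against 0.902 in the next and a median of 0.870.

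The first principal component goes with a fall of at least 4-fold at 3807 regions from its lowest to its highest score. Sequencing depth is argued against: after thinning every library to 1110755 counts the scores correlated with the original ones by 0.9994. The regions that fall had a median level of 2.57 log2 CPM against 3.74 over all regions, but the scores correlated with the original ones by 0.9988 after a loess fit on abundance was removed, which argues against an abundance-dependent trend as the whole cause. Line genotype or the suffix as the whole cause is argued against too, since a share of 0.8929 of the 40320 pairings had a mean score difference as small as the true pairs (exact permutation) and 1 line moved by 1.998 SD of the scores against the mean change with the suffix. Other tissue in the dissection, the stage of the larvae and the quality of the nuclei stay open, as untested, since the labels give no measure of them and no marker regions could be named without an annotation.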

How the results depend on the processing

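The settings with principal components, loess or libraries left out by their score were chosen after seeing the data; the cause of each change was not tested unless stated. The motif and gene list tests and the alternatives to them were not run. Regions differing between lines numbered 29. The count was 1697 with DESeq2, 50 with total counts only, 61 with a mean count of 50 or more, 10 with limma voom, 1 at an adjusted p of 0.01, 69 with no suffix term, 357 in the 16 libraries of the 8 lines, and 0 in edgeR with the X to autosome ratio as a covariate, where 1765 had an unadjusted p under 0.05. It was 3207, 2243 and 1470 with 1, 2 and 3 principal components as covariates, 257 with loess, 3136 with 1 component in the 16 libraries, and 762 without the libraries of negative score. Leaving out single libraries gave 0 to 41. It gave 0 without either library of line DGRP_25208 or replicate 2 of line DGRP_28123, DGRP_29652 or DGRP_55031 (1802 to 2230 at an unadjusted p under 0.05 in edgeR), 1 without either library of line DGRP_28275 or replicate 1 of DGRP_29652, 11 without replicate 1 of DGRP_28123, 13 without replicate 2 of DGRP_28265, and 18 without replicate 1 of DGRP_28265 or replicate 2 of DGRP_28262. Regions differing with the suffix numbered 9. The count was 1114 with DESeq2 (816 higher, 298 lower), 16 with total counts only (15 higher), 19 with a mean count of 50 or more (15 higher), 1 at an adjusted p of 0.01, 1 with the X to autosome ratio as a covariate, 1235 with the first component and 17 with loess. Without the line as a block it was 3691 in 31 libraries and 142 in the same 16. Leaving out single libraries gave 1 to 3, with 3 for either library of line DGRP_28260 and 1 for every other. Line-specific regions summed to 983, to 634 with a mean count of 50 or more, and to 8039 with the first component. The excess correlation of a line's own 2 libraries was 0.0869. It rose to 0.408, 0.333, 0.265, 0.233 and 0.163 with 1, 2, 3, 4 and 5 components removed, the exact permutation p going from 2.48e-05 to 0.0266, and it did not pass with loess (0.0896, exact permutation p = 0.315). Leaving out single lines gave 0.0173 to 0.216, and only without line DGRP_28260 did it pass. The number of arms that differed was 0, and 3 with the first component. Neighbours within 10000 bp had a mean correlation of -0.865 from the 1 called pair, 0.231 over all tested regions and 0.482 over those called with the first component. The last value used line means with the first component and the suffix removed. The named regions kept their line and suffix calls in all 83 and 24 values under other normalizations and filters. The SD of line means is the same under a filter by construction, so there only the call was tried again. limma voom, the X to autosome ratio, an adjusted p of 0.01 and left-out libraries were not among these settings. Of the 29 line calls, limma voom kept 10 and the fit with the X to autosome ratio kept 0. The filter on a mean count of 50 removed 3 named regions and gives no value for them, on 3L at 23829682 and X at 19336717 for lines and on 3R at 14751761 for the suffix. With 7 residual degrees of freedom, the precision of the line test comes from 8 pairs of libraries, and the shallowest of these had 1110755 counts.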

Other observations

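The tests of length, sex composition and a single outlying line below, the tests near the centromere and the correlations of single region pairs were chosen only after the result was seen.

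Some regions on different arms had nearly the same profile over the 23 lines. Of 136 pairs of named regions, 4 on different arms correlated above 0.9. The 3 regions in which line DGRP_28222 was highest, on 3L at 22093911, on 2R at 14464341 and on X at 323469, correlated with r = 0.981 to 0.986 and rho = 0.971 to 0.988, and with r = 0.973 to 0.978 without the 2 lines farthest from the median. The 2 regions with high counts mainly in line DGRP_25194, on 3L at 23829682 and on X at 19336717, had r = 0.958 and rho = 0.864, and r = 0.882 without the 2 farthest lines. Each of the 4 had a permutation p of 1e-05 for r and for rho, the smallest that 100000 permutations can give, with adjusted values over the 136 pairs of 0.000272 and 0.00034.

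Line-differing regions were more frequent near the centromere. In the tenth of each large arm nearest the centromere, 8 of 2472 regions were called between lines against 20 of 28054 elsewhere (odds ratio 4.55, Fisher's exact adjusted p = 0.00781). In the fit with the first component the shares were 16.7% and 9.88%. No region of this part was called on 3R (of 760) or X (of 476) without the component. On 3R alone the shares with it were 7.76% and 8.46% (Fisher's exact adjusted p = 0.580). On X alone they were 25.4% and 10.3% (Fisher's exact adjusted p = 4.56e-18). Neighbouring regions are not independent, so the p-values of these tests can be too small.

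Among the 3207 regions called with the first component as a covariate, 3504 pairs on different arms correlated above 0.9, and they involved 575 regions. The line means used here had the first component and the suffix removed. Chance likeness of regions that vary independently is argued against by at most 12 such pairs in 20 permutations. These shuffled the lines within each region separately. They also break any component that libraries share, so they do not argue against such a component. Sex composition, as far as the X to autosome ratio measures it, is argued against by 100% of the pairs staying above 0.7 (lowest 0.826) with that ratio removed. Line DGRP_25185, which has a single library, added most to 67.8% of the pairs. Without their leading line 98.4% of pairs stayed above 0.7, a limit below the 0.9 that picked them. This argues against 1 outlying line as the whole cause of such pairs, but does not tell lines from libraries. The regions of a pair were alike in length, with a median absolute log2 ratio of 0.4663 against 0.620 in shuffles (permutation p = 0.001, the smallest 1000 shuffles can give), as on 2R from 9989983 to 9992104 and X from 2505241 to 2507100 (r = 0.990). Copies of repeated sequence that share reads may thus account for part of the pattern, as a hypothesis, and a strain difference acting on many loci stays open, as untested.

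Other pairings of the libraries bear on the counts of called regions. In 25 pairings of the libraries of the 8 lines, the real one included, only the real one gave 29 regions, and the highest other gave 5. Once the first component was a covariate, only the real one gave 3207, and the highest other gave 75. The share of 1 in 25 is the smallest these pairings can give. Since the count of 29 fell to 0 or 1 when any 1 of 8 libraries was left out, chance is not firmly excluded for it. For the 3207 the share is also 1 in 25, and only the libraries of the 8 lines were paired anew. The fit with the first component was chosen after seeing the data, and single libraries were not left out of it. Chance is therefore not firmly excluded for the 3207 either. For the suffix, 4 of 100 swaps within lines, the real labels included, gave 9 or more regions, and the highest other gave 7173. That share is under 0.05 by a margin of 1 swap, and the count of 9 fell to between 1 and 3 without single libraries, so chance is not firmly excluded for it. The 3 such swaps had the largest differences in the mean first-component score between the groups, 52.8, 52.9 and 54.8 against 29.3 for the real labels, which points to that structure of the libraries. In the fit with the first component only the real labels gave 1235 regions, and the highest other gave 23.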
